A study of Mus musculus with 2 samples.

How the data were processed

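Messenger RNA levels were measured by RNA sequencing in Lgr5-positive intestinal stem cells sorted from mice by GFP intensity, without culture, per the labels' protocols. One library came from wild-type mice and 1 from mice in which tamoxifen had activated a Cre recombinase to delete floxed Srcap. Both carried Lgr5-Cre. The libraries were single-end, with 50 bp reads made on a BGISEQ-500 instrument and an average of 59000000 reads per sample, per the labels. How many mice or cells went into each library is not given in the sources used here, nor which exons are flanked by loxP sites.

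The authors deposited 1 table of FPKM values per library, per the file headers. FPKM is the number of fragments per kilobase of transcript and 1000000 mapped fragments. HISAT, Bowtie2 and RSEM, without versions or roles, and the build mm10 are named in the submitters' processing notes. The annotation and the counting of strand are not given in the sources used here. Each table holds 17840 rows, in the same order in both, with values given to 2 decimals. Rows above 0 in either library were sorted by the knockout to wild-type ratio with zeros set to 0.01. This order held for 100% of neighbouring rows when it was tested on the tables. Gene symbols had been turned into dates in 27 rows, as spreadsheet programs do, and 2 rows held no symbol. These were renamed through their Entrez identifiers, which failed for 2 of the rows. Of the 17840 identifiers, 17795 matched the NCBI RefSeq gene table of GRCm38.p6, which is the same assembly as mm10 and gave the coordinates. For 121 genes at 1 FPKM or more in both libraries, both values were identical to those of another gene, so levels of near-identical copies (histone, defensin and Tmem254 genes among them) are uncertain.

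Counts were not used here, so the depth was estimated from the steps between low values. FPKM multiplied by transcript length was examined for genes shorter than 900 nucleotides with a single GENCODE M21 transcript. One read was worth about 0.058 FPKM kb in the wild-type library (84 genes) and 0.0595 in the knockout library (87 genes). These steps left 73.8% and 70.1% of values within 0.2 of a whole read. With transcript lengths shuffled over genes and the step fitted anew, 1000 times, the share was at most 64.6% and 64.7%. They imply about 17200000 and 16800000 reads assigned to genes. For a 2 kb transcript, 1 FPKM is then about 34.5 and 33.6 reads. The counting error of a log2 ratio without a pseudocount is about 0.35 at 1 FPKM and 0.16 at 5 FPKM. It is smaller for the ratios used below, to which a pseudocount was added. These figures are approximate, since the lengths used by the authors are not given in the sources used here. They cover counting error only, not the difference between mice.

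With 1 library per genotype no test between genotypes was possible and no p-value is given. Differences are log2 ratios of knockout to wild-type values after adding a pseudocount of 1 FPKM, which understates the change of low genes. A gene was called higher or lower when this ratio was at least 2-fold and the larger value was at least 1 FPKM. Limits such as 2-fold and 4-fold refer to this ratio. Folds printed for single genes are instead ratios of the FPKM values without the pseudocount, and are larger where a value is low. Of 38 gene lists, members with a mean of at least 1 FPKM were used. The median of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list of at least 4 members is said to stand apart when its percentile was below 2.5 or above 97.5. Genes of 1 pathway vary together, so random lists are a narrow yardstick, and the percentile describes this pair of libraries rather than the genotypes. The genes named were Srcap, the 15 with the highest and the 15 with the lowest log2 ratio among genes above 0 in both libraries and at 5 FPKM or more in 1, up to 5 per direction listed at 0 in 1 library, the 10 most abundant in the wild-type library, Prdm16, Rest, Lgr5, Olfm4, Ascl2 and Cpt1a, and up to 4 members per list with the largest absolute ratios. A few genes that the rule names are not reported here. The lists, the rules and most of the other settings were fixed before the data were examined. The other settings were pseudocounts of 0.1 and 5, other expression filters, a 3-fold rule, random lists not matched on expression, and rescaling to a sum of 1000000, to the median or to the upper quartile. A rescaling without Paneth cell secretory genes was added after seeing the data.

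The calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. On simulated data made from the wild-type values for this comparison (11256 genes), the 2-fold rule recovered 100% of 100 genes changed 4-fold and 100% of 100 genes changed 2.83-fold. Of 50 random lists shifted by 0.4, 100% stood apart, and of 50 unshifted lists 8% did. All changed genes and list members were at 5 FPKM or more, and the simulated noise was the same at all levels. This noise was smaller than the robust SD of 0.18 of the real log2 ratios at 10 FPKM or more. Recovery of such large changes was therefore nearly fixed in advance, and differences between mice were not simulated. The simulation therefore does not cover low genes, and 76.6% of the genes called higher were below 5 FPKM in the wild-type library. Mitochondrially encoded genes and Xist were not analysed here.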

Results

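Transcript levels were compared between 1 library of wild-type and 1 library of Srcap-knockout mouse intestinal cells, sorted as Lgr5-positive stem cells. SRCAP is the ATPase of a chromatin remodelling complex that exchanges the histone variant H2A.Z into nucleosomes. Lgr5 marks the stem cells at the base of intestinal crypts. The comparison asks which transcripts differed between these sorted cells after Srcap had been deleted. Both libraries held abundant Paneth cell transcripts, with Defa24 at 14704 and 8425 FPKM against 5.9 and 2.17 FPKM for Lgr5. The differences below are therefore those of the sorted samples as a whole, not of stem cells alone. FPKM values summed to 672183 in the wild-type and 633837 in the knockout library, and 11199 and 11617 genes reached 1 FPKM. The low values imply about 17200000 and 16800000 reads assigned to genes. There were no replicates, so each difference below is between these 2 libraries, and its spread between mice is unknown.

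Srcap (Entrez 100043597, chromosome 7, 127511983 to 127561219, mm10) was at 20.4 FPKM in the wild-type and 11.3 FPKM in the knockout library, which is 55.7% of the wild-type value. Its log2 ratio was -0.79, short of the 2-fold rule. The direction goes with the labels. The gene-level value also counts exons that may lie outside the deleted part, so it does not measure how many cells had lost the gene. The members of the complex were slightly lower as a list and stood apart. Of 11 members, Srcap included, 10 were lower and 0 reached 2-fold, with a median log2 ratio of -0.16 (percentile 0.64 of random lists). H2afz, which encodes H2A.Z, was at 659 and 555 FPKM, and the ATPase Ruvbl1 at 43.7 and 36.8 FPKM. Among other remodelling ATPases and partners of the repressor REST, 1 of 12 was at least 2-fold lower, namely Rest itself, and 11 lay within 2-fold. Chd4 was at 43.1 and 37.2 FPKM, Hdac2 at 33.4 and 29.7 FPKM and Rcor2 at 2.67 and 1.52 FPKM. The median of this list was -0.08, inside the range of random lists (percentile 10.5).

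The libraries were alike for most genes. Of 11784 genes at 1 FPKM or more in either library, 308 were at least 2-fold higher and 49 at least 2-fold lower in the knockout library, while 11427 (97.0%) lay between. For 5766 genes at 10 FPKM or more in both, the median log2 ratio was -0.02, with a robust SD across genes of 0.18. Of the higher genes, 76.6% were below 5 FPKM in the wild-type library. The counts depend on the pseudocount, and were 656 and 110 with 0.1 FPKM and 108 and 23 with 5 FPKM. After rescaling both libraries to a sum of 1000000, 472 genes were higher.

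A small set of transcripts of moderate abundance was many-fold lower in the knockout library. Rxrg, a nuclear receptor that pairs with PPARs (chromosome 1, 167598362 to 167639623), was at 42.0 FPKM in the wild-type and 0.05 FPKM in the knockout library, a level of only a few reads. Smarcd3, a subunit of BAF remodelling complexes, was at 57.4 and 2.31 FPKM, or 24.9-fold lower. Rest, a transcriptional repressor (chromosome 5, 77265494 to 77286432), was 19.7-fold lower, from 27.8 to 1.41 FPKM. The organic cation transporter Slc22a3 was at 15.6 and 0.68 FPKM and the lipoprotein lipase gene Lpl at 18.1 and 1.23 FPKM. Prdm16, a transcription factor known from brown fat and stem cells (chromosome 4, 154316122 to 154637360), was 11.8-fold lower, from 20.9 to 1.78 FPKM. Fabp1, a fatty acid binding protein, was at 97.8 and 16.8 FPKM, and Pparg at 43.6 and 7.15 FPKM. Mmp9, a matrix metalloprotease, was 4.63-fold lower and Sfrp5, a secreted Wnt antagonist, 5.44-fold lower. Also among the 15 lowest were Gm21002, Hist1h2ai, the defensin gene Defa6 and Gm6696, with log2 ratios from -3.30 for Gm21002 to -1.53 for Gm6696. Gm1987 was at 9.1 FPKM, Hist2h3c1 at 3.67, Hist1h4n at 3.1, 0610010B08Rik at 1.87 and Gm3417 at 0.81 FPKM in the wild-type library, and each was listed at 0 in the knockout library.

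Medians of the fatty acid oxidation, PPAR target and regulator lists lay within the range of random lists with members at 1 FPKM or more. Single members lay far lower, Pparg and Fabp1 among them. Rxrb, outside the lists and chosen after its values were seen, was at 86.6 and 41.5 FPKM (log2 ratio -1.04). Of 8 regulators around PRDM16 and the PPARs, 7 were measured and 2 were at least 2-fold lower, Prdm16 and Pparg. Ppard was at 114 and 65.6 FPKM and Rxra at 23.0 and 27.0 FPKM, and the list median was 0.01 (percentile 52.4). Among members at 5 FPKM or more, this median became -0.39 and the list stood apart (percentile 0.0). Of 16 measured PPAR target genes, 2 were at least 2-fold lower, Fabp1 among them, and 0 were higher. Creb3l3 was at 1.64 and 3.48 FPKM and Slc27a4, a fatty acid transporter, at 17.9 and 30.4 FPKM. Their median log2 ratio was 0.09, within the random range (percentile 87.5). All 19 fatty acid oxidation enzymes lay within 2-fold, with a median of 0.04 (percentile 82.1). Cpt1a, which controls entry of fatty acids into mitochondria (chromosome 19, 3322326 to 3385735), was at 72.7 and 56.0 FPKM, with a log2 ratio of -0.37. Acsl1 was at 12.7 and 9.54 FPKM, while Slc25a20 was at 15.3 and 19.7 FPKM and Acadl at 33.2 and 41.9 FPKM.

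Markers of Lgr5-positive stem cells were lower in the knockout library. Of 21 markers, 20 had a negative log2 ratio, 3 were at least 2-fold lower and 0 higher, and the median was -0.62, below all 10000 random lists. Olfm4 was 2.57-fold lower, from 1457 to 568 FPKM. Lgr5 (chromosome 10, 115450314 to 115587780) was 2.72-fold lower, from 5.9 to 2.17 FPKM. The RNA-binding protein gene Msi1 was at 14.6 and 6.73 FPKM, Gkn3 at 4.0 and 1.56 FPKM, and the stem cell transcription factor Ascl2 at 19.1 and 10.7 FPKM. Wnt target genes, of which several are also stem cell markers, had a median of -0.24 (percentile 0.01), with 14 of 14 negative and only Lgr5 at least 2-fold lower. Ephb3 was at 16.3 and 11.1 FPKM and Nkd1 at 1.58 and 0.91 FPKM. Notch pathway genes had a median of -0.17 (percentile 1.19, but 5.3 without the filter on members), with 0 of 8 past 2-fold, and Hes1, a Notch target, was at 40.8 and 29.5 FPKM. Dll1, a Notch ligand, was at 16.6 and 13.0 FPKM. Only 3 reserve stem cell markers were measured, under the minimum of 4 for standing apart, and their median was -0.33 (percentile 0.78). Lrig1 was at 49.4 and 38.3, Hopx at 152 and 121 and Bmi1 at 5.43 and 4.91 FPKM. BMP pathway genes had a median of 0.24 (percentile 97.3, inside the range, but 99.42 with a pseudocount of 5 FPKM), and 1 of 8 was at least 2-fold higher, Bmp4 at 0.53 and 2.56 FPKM.

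Markers of differentiated lineages differed in direction. Paneth cell markers were lower, with 12 of 12 negative, 1 at least 2-fold lower and a median of -0.81, below all 10000 random lists. The defensin gene Defa24 was the most abundant transcript of both libraries, at 14704 and 8425 FPKM. Of other Paneth cell products, Defa17 was at 8607 and 4779 FPKM and the lysozyme gene Lyz1 at 5797 and 3191 FPKM, whereas Lgr5 itself was at 5.9 and 2.17 FPKM. The 27 Paneth cell secretory genes held 12.7% of all FPKM in the wild-type and 8.17% in the knockout library. Also among the 10 most abundant were Defa2, Defa-rs7, Gm15284, Defa20 and Gm15308, with log2 ratios from -1.15 for Defa20 to -0.10 for Gm15308, and Eef1a1 and Rpl41 at -0.22 and -0.16. Defa23, in contrast, was at 0.31 and 21.8 FPKM, but reads of defensin genes can be split between near-identical copies. Enteroendocrine markers had a median of -0.38, below all random lists, with 12 of 15 negative and 2 at least 2-fold lower. These were the hormone genes Gip, at 107 and 39.5 FPKM, and Ghrl, at 43.8 and 16.5 FPKM. Chga was at 95.6 and 57.6 FPKM. Tuft cell markers had a median of -0.22 (percentile 0.14), with 0 of 10 past 2-fold, and their regulator Pou2f3 was at 3.05 and 1.61 FPKM. Enterocyte markers were higher, with 16 of 17 positive, 5 at least 2-fold higher and a median of 0.68, above all random lists. The aminopeptidase gene Anpep was at 72.6 and 201 FPKM, sucrase-isomaltase (Sis) at 6.5 and 18.7 FPKM and Krt20 at 60.8 and 146 FPKM. Goblet cell markers had a median of 0.63, above all random lists, with 7 of 9 positive and 1 at least 2-fold higher, Zg16 at 668 and 1648 FPKM. The mucin gene Muc2 was at 112 and 176 FPKM.

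**Figure D1:**
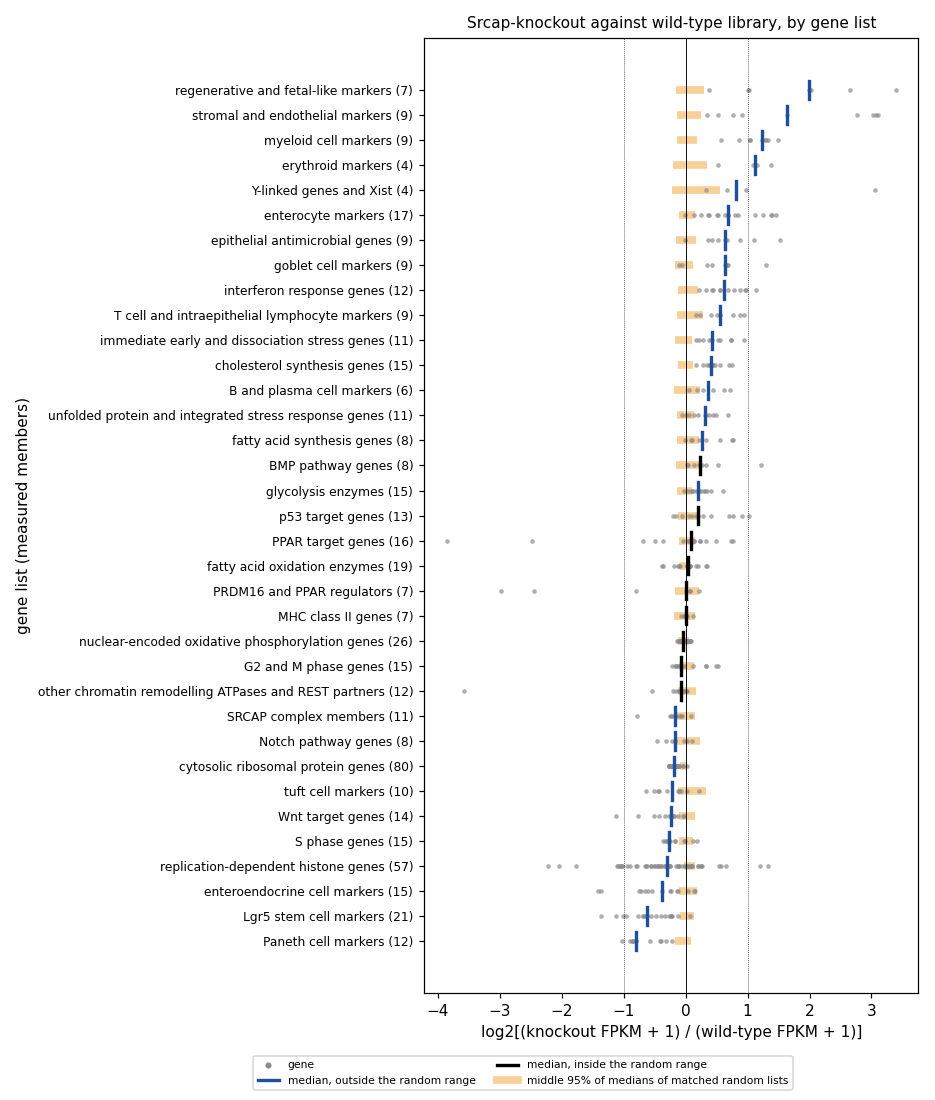
Log2 ratio of knockout to wild-type FPKM (pseudocount 1 FPKM; x axis) for the measured members of each gene list (grey points; y axis, number of members in brackets), with the list median as a vertical bar and the middle 95% of medians of matched random lists as an orange band; 1 library per genotype. Paneth cell (-0.81) and stem cell markers (-0.62) have the lowest medians and regenerative (1.995) and stromal markers (1.63) the highest, while the median of PPAR target genes (0.09) lies within the band, with 2 members far below it.

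Stromal and myeloid markers were higher in the knockout library. Among the genes with the highest ratios, the acute phase gene Saa3 was at 0.80 FPKM in the wild-type and 256 FPKM in the knockout library. Complement C3 was 32.4-fold higher, from 9.04 to 293 FPKM, and the complement inhibitor gene Serping1 9.34-fold higher, from 7.0 to 65.4 FPKM. The mesothelial genes Msln and Upk3b were 20.9-fold and 20.6-fold higher, from 0.92 to 19.2 FPKM and from 1.27 to 26.1 FPKM. The collagen genes Col1a1 and Col1a2 were 11.1-fold and 11.3-fold higher and the proteoglycan gene Dcn was 9.26-fold higher, from 8.94 to 82.8 FPKM. Rarres2 was 14.1-fold, Slpi 10.2-fold and Tmem254b 8.83-fold higher. Nkain4 was 25.1-fold higher, from 0.40 to 10.05 FPKM, and Chil1 69.0-fold, from 0.26 to 17.9 FPKM. With the pseudocount, their log2 ratios were 2.98 and 3.91. Ccl21a at 35.4 FPKM, Sprr2a2 at 16.2, Hist2h2aa2 at 1.41, Cldn10 at 1.34 and the Y-linked Sly at 1.06 FPKM were listed at 0 in the wild-type library. Stromal and endothelial markers had a median log2 ratio of 1.63, with 5 of 9 at least 2-fold higher, Col3a1 among them at 4.48 and 36.2 FPKM. Myeloid markers had a median of 1.23, with 7 of 9 at least 2-fold higher. C1qa was at 33.5 and 85.3 FPKM and Fcer1g at 7.57 and 23.2 FPKM. Both medians lay above all 10000 random lists. T cell markers had a median of 0.55 (percentile 99.96) and B and plasma cell markers one of 0.36 (percentile 99.6), with 0 of 9 and 0 of 6 past 2-fold. Gzmb was at 9.83 and 19.9 FPKM and Jchain at 335 and 518 FPKM. Of 4 erythroid genes 3 were at least 2-fold higher (median 1.12), with Hba-a1 at 19.8 and 45.6 FPKM. The 1 pancreatic acinar gene measured, Cela1, was at 6.17 and 5.95 FPKM.

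Regenerative and fetal-like markers were higher together with these stromal and myeloid markers. Of 7 measured, 6 were at least 2-fold higher, with a median of 1.995, above all random lists. Clu was at 2.42 and 20.6 FPKM, Anxa1 at 1.26 and 8.17 FPKM and Ly6a at 28.4 and 116 FPKM, and Msln is also a mesothelial gene. Interferon response genes had a median of 0.62, with 12 of 12 positive and 1 at least 2-fold higher, Irf7 at 29.5 and 65.8 FPKM. Zbp1, a nucleic acid sensor, was at 16.9 and 34.3 FPKM. Without the pseudocount, Ifit1 (2.80-fold), Ifit3 (2.34-fold) and Zbp1 (2.03-fold) were past 2-fold as well. Epithelial antimicrobial genes had a median of 0.64, with 2 of 9 at least 2-fold higher. These were Lcn2, at 1.62 and 6.55 FPKM, and the lectin gene Reg3b, at 1928 and 4133 FPKM. Reg3g was at 1231 and 2257 FPKM. The interferon and antimicrobial medians lay above all random lists. MHC class II genes were nearly equal, with a median of 0.00 (percentile 66.3) and Cd74 at 2157 and 2186 FPKM.

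**Figure D2:**
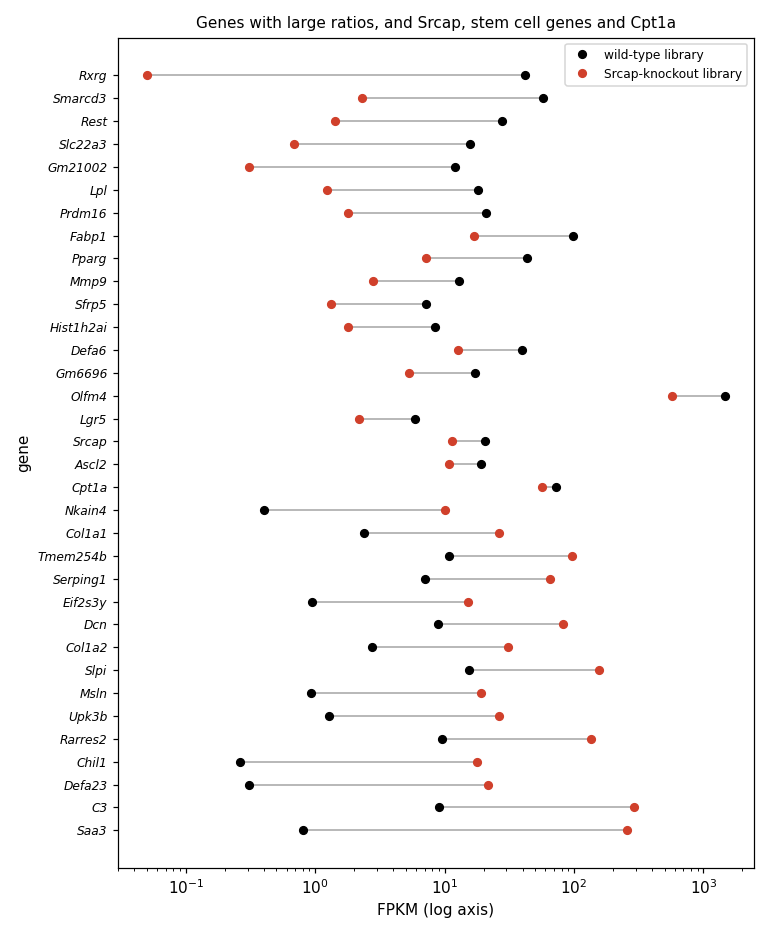
FPKM in the wild-type (black) and Srcap-knockout (red) library, on a log axis, for genes among the 15 with the lowest and the 15 with the highest log2 ratios and for Srcap, Lgr5, Olfm4, Ascl2 and Cpt1a; each point is 1 library. Rxrg spans 42.0 to 0.05 FPKM and Saa3 0.80 to 256 FPKM, while Srcap lies at 20.4 and 11.3 FPKM.

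With the pseudocount of 1 FPKM, the listed proliferation, p53 and metabolism genes differed by less than 2-fold, except for Cdkn1a. S phase genes had a median of -0.26, below all random lists, with 13 of 15 negative. The replication helicase gene Mcm6 was at 79.8 and 61.9 FPKM and Mcm2 at 54.0 and 42.7 FPKM. Genes of G2 and M phase had a median of -0.08 (percentile 10.2), with Mki67, the opposite in sign, at 13.0 and 19.2 FPKM. Targets of p53 had a median of 0.20 (percentile 96.9, inside the range, but outside it under 3 alternatives, such as 99.45 with a pseudocount of 0.1 FPKM), and 1 of 13 was at least 2-fold higher, the cell cycle inhibitor Cdkn1a at 33.0 and 67.8 FPKM. Fas was at 2.31 and 5.22 FPKM, or 2.26-fold higher without the pseudocount. Glycolysis enzymes had a median of 0.20 (percentile 99.9), with Pfkp at 31.8 and 48.9 FPKM. Nuclear-encoded oxidative phosphorylation genes were close to equal, with a median of -0.04 (percentile 48.8) and 0 of 26 past 2-fold, and Ndufa2 was at 176 and 162 FPKM. Cholesterol synthesis genes were higher together, with 15 of 15 positive and a median of 0.42, above all random lists. Hmgcs1 was at 31.6 and 53.7 FPKM and Msmo1 at 40.1 and 59.5 FPKM. Fatty acid synthesis genes had a median of 0.27 (percentile 99.0, but 96.89 among members at 5 FPKM or more), with Scd2 at 48.6 and 82.4 FPKM and Scd1 at 1.75 and 3.69 FPKM, or 2.11-fold higher without the pseudocount.

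Stress genes were moderately higher and ribosomal genes slightly lower. Immediate early and dissociation stress genes had a median of 0.42, above all random lists, with 11 of 11 positive and 0 past 2-fold. Atf3 was at 185 and 356 FPKM and Fosb at 239 and 400 FPKM. Genes of the unfolded protein and integrated stress responses had a median of 0.32 (percentile 99.97), with Chac1 at 4.13 and 7.28 FPKM. Cytosolic ribosomal protein genes had a median of -0.19, below all random lists, with 79 of 80 negative and a range from -0.27 to 0.01. Rpl4 was at 1469 and 1221 FPKM. Replication-dependent histone genes had a median of -0.30, below all random lists, with 9 of 57 at least 2-fold lower and 2 higher. Their values rest on near-identical copies and on how much RNA without a poly(A) tail was captured. The 4 Y-linked genes all had positive log2 ratios, with a median of 0.82 (percentile 99.7), and 1 was at least 2-fold higher. Without the pseudocount, Eif2s3y was 16.2-fold higher, from 0.94 to 15.2 FPKM, and Kdm5d 2.75-fold, from 1.24 to 3.41 FPKM. Ddx3y was at 2.33 and 4.28 and Uty at 1.33 and 1.92 FPKM. With 1 library per genotype, and Xist not analysed, a difference in the sex of the mice cannot be told apart from one of genotype. Of the 35 lists with at least 4 measured members, 10 stood apart as lower and 16 as higher, where 1.75 would by chance if genes varied independently.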

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

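The rescaling without Paneth cell secretory genes was chosen after seeing the data, and the other alternatives before. The number of genes at least 2-fold higher in the knockout library was 308. It was 656 and 108 with pseudocounts of 0.1 and 5 FPKM, 121 where the larger value had to reach 10 FPKM, 99 under a 3-fold rule and 472 after rescaling both libraries to a sum of 1000000. The number at least 2-fold lower was 49. It was 110 and 23 with the pseudocounts, 30 with the minimum of 10 FPKM and 16 under the 3-fold rule. Removing the filter on low values left these counts as they were, since a pseudocount of 1 FPKM already keeps a gene under 1 FPKM from reaching 2-fold. No scaling moved the median log2 ratio of genes at 10 FPKM or more by over 0.1, from -0.02 to at most 0.07. The share of calls that were higher was 86.3% as deposited and at most 90.2%. The log2 ratio of Srcap and the medians of stem cell markers, PPAR target genes and fatty acid oxidation enzymes kept their side of the rule under each alternative. Of 178 named genes, 13 crossed 2-fold with a shift above a set minimum, 12 of them with a pseudocount of 5 FPKM and 1 with 0.1. Crossings with a smaller shift were not counted, so more genes than these crossed 2-fold, Fas with a pseudocount of 0.1 FPKM among them. Where past 2-fold, 0 changed sign. This was fixed in advance, since a pseudocount cannot change a sign and the rescalings were small. Of 35 lists 0 that stood apart changed sign, and 5 crossed the limit of the random range under some alternative. They were the PRDM16 and PPAR regulators, the Notch, BMP and p53 lists and fatty acid synthesis. No paired analysis was possible because there was 1 library per genotype, and for the same reason no replicate could be left out. Depth limits genes below about 1 FPKM. At 1 FPKM, counting error alone gives a log2 ratio without the pseudocount an error of about 0.35 for a 2 kb transcript.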

Other observations

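Fabp6, the ileal bile acid binding protein, was at 305 FPKM in the wild-type and 1426 FPKM in the knockout library and was chosen after its values were seen. Other genes of the distal small intestine with a mean of at least 1 FPKM, 5 in number, had log2 ratios from 0.34 to 1.8, and 6 proximal genes had ratios from -0.48 to 1.47.

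In the paragraphs below, the tests on uninspected mesothelial and fibroblast markers, their distance to lymphocyte markers and the distal against proximal genes were set before their values were seen. The other tests were chosen after.

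A set of 9 genes at 15 FPKM or more in the wild-type library were at least 4-fold lower in the knockout library (among them Rxrg, Smarcd3, Rest, Slc22a3, Lpl, Prdm16, Fabp1 and Pparg). Among 3693 genes at the same wild-type levels, the 9 included, the next lowest log2 ratio was -1.56. The limits were set after the values were seen, and this gap depends on them. Just below 15 FPKM, Gm21002 (11.9 FPKM, log2 ratio -3.30) and Mmp9 (12.9 FPKM, -1.88) were also low. Counting error is argued against, since at the estimated depth it would be expected to bring 0.15 genes past both limits, over 17284 genes with their shortest annotated transcript as the length. No stem cell marker fell as far as the 9 genes, since the lowest was at -1.36, against -2.45 for the highest of the 9. The lower quartile of these markers was -0.69, or 1.76 above that highest ratio. The 9 genes were chosen for low ratios and the marker values had been seen, so this gap was largely fixed in advance. It does not decide whether fewer stem cells in the knockout sample contributed. Several of the 9 belong to PPAR signalling, yet the 14 PPAR target genes outside the set had a median of 0.14 and a lower quartile of -0.01. Leaving out targets chosen for low ratios favours this outcome. All 16 measured targets, these included, had a median of 0.09 and a lower quartile of -0.40. These values argue against a decline of all PPAR targets, not against a decline of some. An effect of Srcap loss on these genes alone, a feature of either library and an error in the tables all stay open and untested, since there is 1 library per genotype and the reads were not analysed here.

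Mesothelial, fibroblast and myeloid transcripts were higher in the knockout library. Of 14 measured mesothelial and fibroblast markers that had not been inspected, 14 were higher and 10 at least 2-fold, with a median log2 ratio of 1.41 (Sparc at 10.4 and 47.8 FPKM, Gsn at 23.2 and 50.6 FPKM, Gpm6a at 0.54 and 5.99 FPKM), which is consistent with more such cells in the knockout sample, although sorting by GFP should remove them. A difference in FPKM scaling is argued against by the median of -0.02 over genes at 10 FPKM or more. A lower epithelial share that raised all other types alike is argued against by the lower quartile of these markers lying 0.11 above the upper quartile of lymphocyte and plasma cell markers, a narrow margin. The regenerative markers Clu, Anxa1, Ly6a and Msln can come from these cells too, so an epithelial response to Srcap loss stays open and untested.

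Stem cell, Paneth and enteroendocrine markers were lower while enterocyte and goblet markers were higher. The smaller share of Paneth cell transcripts in the FPKM total would shift all other transcripts by 1 factor (0.07 on the log2 scale). This is argued against for the other markers, since the lower quartile of enterocyte and goblet markers lay 0.6 above the upper quartile of stem cell and enteroendocrine markers. Knockout cells taken from a more distal part of the intestine cannot be told apart from other causes. The 5 distal genes had a median 0.89 above that of 6 proximal genes, between the bounds set in advance of 1 and 0.3. Of the proximal genes, Slc40a1 (log2 ratio 1.14) and Gsta1 (1.47) were at least 2-fold higher. Cybrd1 (0.99), at 0.60 and 2.18 FPKM, fell just short with the pseudocount. Gata4 (-0.48), Ada (-0.30) and Onecut2 (-0.26) had negative ratios within 2-fold. A change of cell fate after Srcap loss, fewer Paneth cells or a shifted sorting gate stays open and untested.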
